A study of Mus musculus with 32 samples.

How the data were processed

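The samples were olfactory bulbs of mice on a mixed strain background, and total RNA had been labelled as biotinylated cRNA and hybridized to Illumina mouse bead arrays. According to the labels, the authors extracted signals with GenomeStudio, whose version is not given in the sources used here. The deposited raw table holds an average signal intensity and a detection p-value for each of 25697 probes on 32 arrays, per the file headers, without background subtraction. The deposited normalized table holds an intensity that, from its values, had been quantile normalized over all 32 arrays and background subtracted, with 25.7% of the values below 0. It ranked the probes of each array as the raw table did and was used as an alternative only. Of the probes, 23978 carried 1 gene name, 0 carried several and 1719 carried none, which left 16593 named genes. No symbol needed updating. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and only the order of genes on chromosome 18 was used.

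Raw intensities were processed with neqc in limma, which infers the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. The arrays of each age were processed among themselves for the mutant comparisons, and all 32 together for the difference between the ages and the comparison of the controls. A probe entered when its detection p was under 0.05 on at least 4 arrays of the fit. Each gene was represented by the probe with the highest mean, a choice blind to genotype, and unnamed probes were kept as they were. This left 14455 probes and 10852 genes at E18.5, 12950 probes and 9928 genes at P30, and 15105 probes and 11312 genes over both ages. Differences were tested with limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05, and for the age comparison also a change of at least 2-fold. A gene not detected on any array of a group was given as a bound on its fold change. Values are means ± SD or changes with the standard error of the fit.

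The 28 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists cover the Tshz family, olfactory interneuron lineage transcription factors, GABA synthesis and transport, periglomerular and dopaminergic cells, granule cells, migration cues and receptors, neuroblasts and immature neurons, synapses and mature neurons, proliferation, radial glia and stem cells, mitral and tufted cells, olfactory sensory neuron axons, olfactory ensheathing glia, oligodendrocytes and myelin, astrocytes, microglia, endothelium and pericytes, meninges and fibroblasts, cortical excitatory neurons, striatal and septal neurons, blood, sex-linked genes, immediate early genes, neuropeptides, p53 targets and apoptosis, Wnt, Shh and BMP pathway targets, stress response and RNA quality, and reference genes. Each list with at least 3 measured members was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Members were counted after adjustment over all genes and after adjustment over the list alone. The rule named the 10 largest rises and falls past the threshold with the same direction within both chips, the 2 smallest p of each list, and for the difference between the ages the 5 smallest p in each direction. Zfp236, Neto1, Kcnh3 and Snx7 at E18.5 and the other list members named beside the counts, such as Trh, Ddc, Pbx3, Npas4, Cxcr4, Cartpt, Doc2g, C1qb, Trem2, Mef2c and Msx1, were chosen after their values were seen.

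Samples of the same replicate number lay on the same chip. At E18.5 the deviations of a control and a mutant from their group means correlated with r between 0.118 and 0.355 in all 8 pairs. Within chips r lay between -0.08 and 0.303, and 2 controls and 3 mutants correlated best with their own number. How much of this came from the number and how much from the chip was not settled. Replicate number and chip were therefore used as blocks in alternatives. It is not stated that replicates are separate animals, so p values measure only the spread between these samples. In a self-test on simulated values with the means and spreads of the tested genes and known changes added, 92.5% of 2-fold changes were recovered at E18.5, 80.6% at P30, 58.2% for the difference between the ages and 53.7% for the age comparison. Of 1.5-fold changes, 68.7%, 23.9%, 13.4% and 0% were recovered, the last lying under the 2-fold condition of that comparison. The fits made 15, 5, 6 and 1 false calls. A list shifted by 0.5 on the log2 scale was called in each with 0 other lists. The simulated genes varied independently of each other and of chip, so false calls of lists with correlated members were not tested. In each fit 67 genes were changed 1.5-fold, 67 2-fold and 66 3-fold. The adjusted threshold is stricter where fewer genes change strongly. These shares may therefore overstate recovery in the real E18.5 comparison, where 63 genes passed. The analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.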

Results

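Gene expression was measured in 32 samples of mouse olfactory bulb, with 1 bead array per sample and 8 arrays in each of 4 groups. The olfactory bulb is the part of the forebrain that receives the axons of the olfactory sensory neurons, and its granule and periglomerular interneurons are mostly GABAergic cells that reach the bulb by migration. Tshz1 encodes a zinc finger transcription factor. At E18.5, shortly before birth, the controls carried a GFP allele and a wild-type allele of Tshz1 and the mutants a GFP allele and a delta allele. At P30, in young adults, all samples carried Nestin-Cre, the controls with a flox and a wild-type allele and the mutants with a flox and a GFP allele. The P30 labels are those that the submitters later exchanged between control and mutant. No probe used here was named Tshz1 or Tshz2, so the labels were not checked against the level of the targeted gene.

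On the arrays, 51.7% ± 1.8 (SD, n = 8) of the probes were detected above background in E18.5 controls, 52.6% ± 1.7 in E18.5 mutants, 45.6% ± 2.1 in P30 controls and 45.7% ± 3.7 in P30 mutants. The share of detected probes did not separate mutants from controls at E18.5 (exact permutation p = 0.295, two-sided) or at P30 (exact permutation p = 0.93, two-sided). Median raw intensities lay between 132 and 181 at E18.5 and between 100.2 and 130 at P30. Each age occupied its own 2 chips, each with 4 controls and 4 mutants, so age could not be told apart from chip. The number of arrays limits the precision of every value given here.

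The first comparison asked which transcripts differed in the Tshz1 mutant bulb shortly before birth. In the E18.5 mutants, genes for GABA synthesis and transport and the granule cell markers Gng4 and Nrgn were lower, and few genes were higher. With an estimated correlation the GABA list passed (adjusted p = 0.0108) and the granule cell list did not (adjusted p = 0.126). The largest fall was that of C1ql2, which encodes a secreted C1q-like protein of synapses, from 8.76 ± 0.35 to 6.02 ± 0.31 (log2 normalized intensity, mean ± SD, n = 8 per group), a 6.68-fold lower level (limma adjusted p = 4.65e-09). Prokr2, the receptor for a secreted cue that guides migrating olfactory neuroblasts, fell from 9.71 ± 0.27 to 8.50 ± 0.29, a 2.31-fold lower level (limma adjusted p = 8.64e-05). Th, the rate-limiting enzyme of dopamine synthesis, fell from 9.25 ± 0.37 to 8.44 ± 0.14, a 1.76-fold lower level (limma adjusted p = 0.00464). Th did not pass with median scaling (adjusted p = 0.0549), over a range of 0.00314 to 0.822 in its 8 alternatives. For each of these genes all 8 mutants lay below all 8 controls.

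Of 10852 genes tested at E18.5, 63 passed the threshold, 8 higher and 55 lower in the mutants, and 11 of those that fell did so by at least 2-fold while 0 rose that far. Besides C1ql2 and Prokr2, the 10 largest falls were those of Ntsr1, a neurotensin receptor (log2 change -1.85), Crabp1, a retinoic acid-binding protein (-1.69), and Cpa3, a carboxypeptidase of mast cells (-1.63). Sp7, a zinc finger transcription factor best known from bone (-1.59), Adamts19, a secreted metalloprotease (-1.52), an unnamed probe (-1.43), Crhbp, a binding protein of corticotropin-releasing hormone (-1.18), and Nmbr, a neuromedin B receptor (-1.13), completed them. Their standard errors lay between 0.11 and 0.32. Detection on the 8 mutant arrays was partial for C1ql2 (6), Crabp1 and Crhbp (5 each) and Adamts19 and Nmbr (7 each). Cpa3 was read by 3 probes, and when every probe was tested on its own the other two gave -1.46 (adjusted p = 0.078) and -0.36 (adjusted p = 0.582).

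The 8 genes that rose at E18.5 included Creg2 (log2 change 0.94), Mettl8, an RNA methyltransferase (0.86), Npr3, the clearance receptor of natriuretic peptides (0.76), Fhdc1, a formin-related protein (0.72), Tfap2b, an AP-2 transcription factor (0.61), Pgm5 (0.60) and an unnamed probe (0.46). Wnt9b, a secreted Wnt ligand, was detected on 0 of 8 control arrays and on 7 of 8 mutant arrays and was at least 1.11-fold higher in the mutants (limma adjusted p = 0.00395). With the replicate number as a block, Creg2 (adjusted p = 0.0791), Tfap2b (adjusted p = 0.109), Pgm5 (adjusted p = 0.0611) and the unnamed probe (adjusted p = 0.0855) no longer passed. When every probe was tested on its own, the other Pgm5 probe gave 0.20 (adjusted p = 0.683) and the other Tfap2b probes 0.46 (adjusted p = 0.298) and 0.42 (adjusted p = 0.396). Npr3 was detected on 4 of 8 control arrays.

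Among the fixed gene lists at E18.5, genes for GABA synthesis and transport fell as a group (camera adjusted p = 0.000163, or adjusted p = 0.0108 with an estimated correlation, and 4.12e-05 to 0.0358 over 26 alternatives). Of 5 measured members, 2 fell, and the same number fell adjusted over the list alone: Gad1, a GABA-synthesizing enzyme (log2 change -0.63, SE 0.13), and Slc32a1, the vesicular GABA transporter (-0.48, SE 0.09; adjusted p = 0.0611 with the replicate block). When every probe was tested on its own, the other Gad1 probe gave -0.55 (adjusted p = 0.0528). The mean of the list lay lower in all 8 mutants than in every control (-0.35, SE 0.05 over arrays), by -0.29 on chip A and -0.42 on chip B. Granule cell markers also fell as a group, with a list mean of -0.27 (SE 0.07), -0.28 on chip A and -0.26 on chip B (camera adjusted p = 0.0119, but adjusted p = 0.126 with an estimated correlation). Of 6 measured members 2 fell, also 2 adjusted over the list alone: Gng4, a G protein gamma subunit (-0.71, SE 0.10), and Nrgn, the postsynaptic calmodulin-binding protein neurogranin (-0.82, SE 0.16). These 2 members made up most of the list mean. The granule cell list did not pass on chip A alone (adjusted p = 0.0788) or without control replicate 4 (adjusted p = 0.0527), control replicate 5 (adjusted p = 0.0606) or mutant replicate 6 (adjusted p = 0.0503). Over all 26 alternatives its adjusted p ran from 0.00282 to 0.126.

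The proliferation list rose as a group at E18.5 by a small amount, with a mean of 0.18 (SE 0.06), 0.16 on chip A and 0.21 on chip B. The test gave a camera adjusted p = 0.000589 (but adjusted p = 0.266 with an estimated correlation, over a range of 5.26e-05 to 0.266). None of its 15 measured members passed on its own (1 rose adjusted over the list alone), yet all 15 had positive changes. The smallest p was that of Top2a, a topoisomerase of dividing cells (log2 change 0.42, adjusted p = 0.0567). Immediate early genes, which neurons transcribe after activity, fell as a list by -0.23 (SE 0.08), -0.25 on chip A and -0.21 on chip B (camera adjusted p = 0.0377, but adjusted p = 0.367 with an estimated correlation). No member of 8 passed (1 fell adjusted over the list alone), and all 8 changes were negative. This list did not pass with chip as a block (adjusted p = 0.061), with the replicate block (adjusted p = 0.0726), or without control replicate 3 (0.12), 4 (0.14), 5 (0.0827) or 6 (0.0771) or mutant replicate 6 (adjusted p = 0.152). The 26 alternatives ran from 0.00842 to 0.367.

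In the remaining lists at E18.5, camera gave no group change over all arrays, and 4 lists had 1 member each that fell. Th fell among 9 periglomerular and dopaminergic markers (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.67). Prokr2 fell among 20 migration cues and receptors (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.429). Camk2a, a synaptic kinase subunit, fell among 13 genes of synapses and mature neurons (2 fell adjusted over the list alone; camera adjusted p = 0.429). Cck fell among 10 neuropeptides (1 fell adjusted over the list alone; camera adjusted p = 0.915). Camk2a changed by -0.80 (SE 0.16) on the brighter probe and by -0.43 on the other (adjusted p = 0.719 when every probe was tested), and Cck by -0.58 (SE 0.11). No member passed among 13 interneuron lineage transcription factors (1 rose adjusted over the list alone; camera adjusted p = 0.474). Tshz3, the measured member of the Tshz family, changed by 0.30 (SE 0.10, adjusted p = 0.299, and rose adjusted over the list alone, where it is the 1 member). The lists for radial glia and stem cells, neuroblasts and immature neurons, mitral and tufted cells, olfactory sensory neuron axons, olfactory ensheathing glia, oligodendrocytes and myelin, astrocytes, microglia, endothelium and pericytes, and meninges and fibroblasts had 0 members past the threshold, also 0 adjusted over the list alone. The same was true of the lists for cortical excitatory neurons, striatal and septal neurons, blood, sex-linked genes, p53 targets and apoptosis, Wnt, Shh and BMP targets, stress and RNA quality, and reference genes. Camera adjusted p in all of these lay between 0.187 and 0.97. Over arrays, only the radial glia list (mean 0.12, SE 0.04) and the cortical list (mean 0.11, SE 0.03) had an unadjusted p under 0.05 among them. Both were higher in the mutants (exact permutation p = 0.00124 and 0.00326, two-sided). The meningeal list was higher without control replicates 6 and 8 (adjusted p = 0.0192), over a range of 0.0192 to 0.593 in 26 alternatives.

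Chip B alone called 5 genes and chip A alone 41, with 4 arrays per genotype each, and chip as a fixed block called 75 (11 higher, 64 lower). Without control replicates 6 and 8, which lay farthest from the other arrays on the first principal component, 50 genes passed, 46 of them among the 63. Creg2, Tfap2b, Pgm5, the unnamed probe that rose, Cpa3, Gad1, Nrgn, Camk2a and Cck were the 9 of 25 named genes that no longer did.

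**Figure D1:**
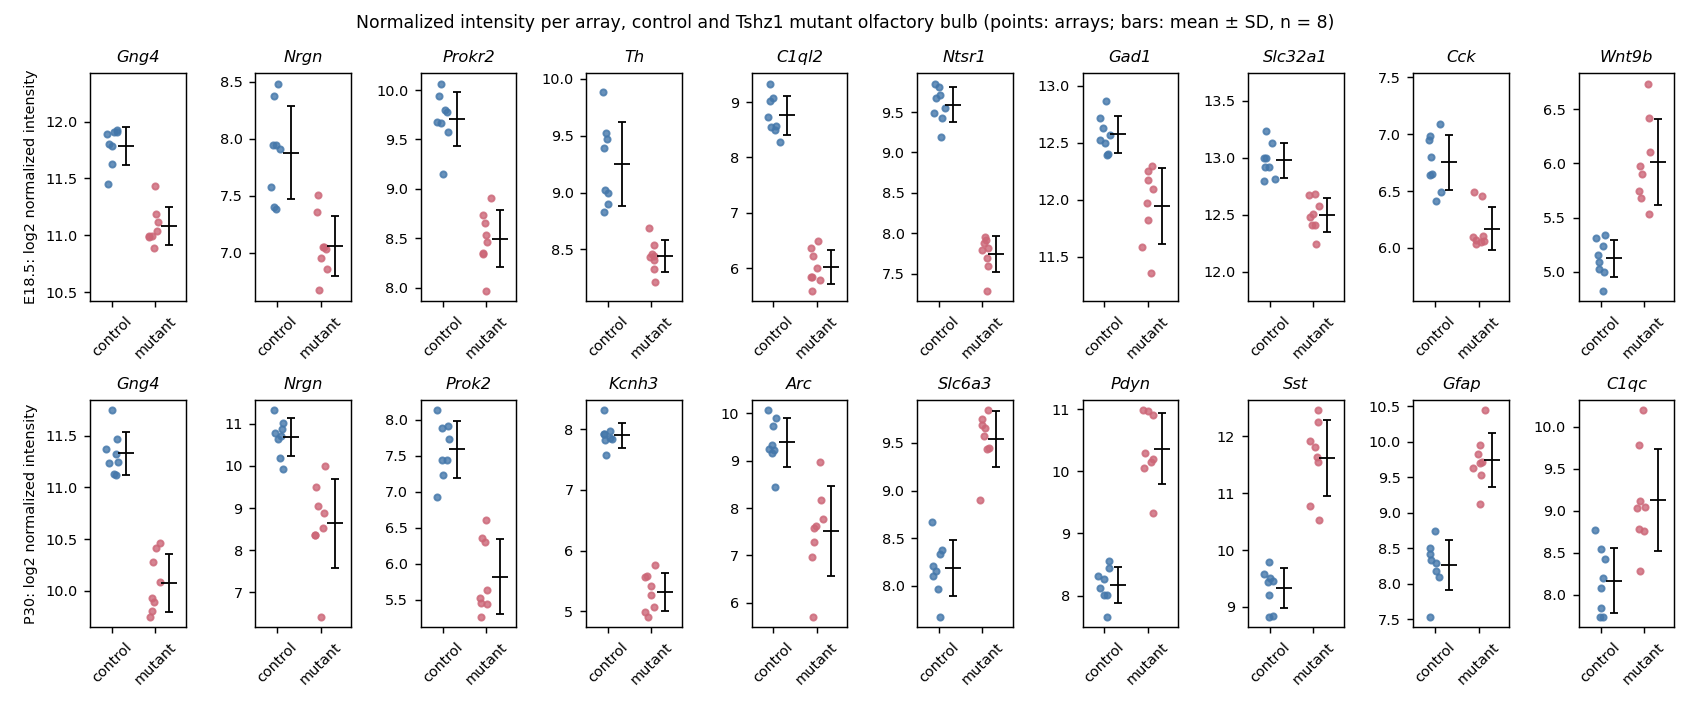
Log2 normalized intensity of selected genes on each array (vertical axes) in control and Tshz1 mutant bulbs (horizontal axes), E18.5 in the upper row and P30 in the lower row; points are arrays and bars the mean ± SD of 8. C1ql2, Ntsr1 and Prokr2 at E18.5 and Kcnh3, Slc6a3, Pdyn and Gfap at P30 show no overlap between the groups.

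The second comparison asked the same question in the bulb of young adults, with Tshz1 removed through Nestin-Cre. In the P30 mutants, the granule cell list, through Nrgn, Gng4 and Pbx3, and immediate early genes were lower. Neuropeptides and the markers of microglia, astrocytes, dopaminergic periglomerular cells and other cell groups were higher. With an estimated correlation the granule cell and neuropeptide lists passed (adjusted p = 0.0113 each). The immediate early, microglial and astrocyte lists (adjusted p = 0.057 each) and the periglomerular list (adjusted p = 0.0886) did not. Gng4 fell from 11.33 ± 0.21 to 10.08 ± 0.28 (log2 normalized intensity, mean ± SD, n = 8 per group), a 2.38-fold lower level (limma adjusted p = 1.66e-05). Pdyn, which encodes the opioid peptide precursor prodynorphin, rose from 8.17 ± 0.29 to 10.36 ± 0.57, a 4.55-fold higher level (limma adjusted p = 7.55e-07). A second Pdyn probe rose by 0.80 on the log2 scale (adjusted p = 0.0182 when every probe was tested). Gfap, an intermediate filament protein of astrocytes, rose from 8.26 ± 0.36 to 9.74 ± 0.38, a 2.8-fold higher level (limma adjusted p = 2.21e-05), and in all 3 of these genes the 8 mutants did not overlap the 8 controls.

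Of 9928 genes tested at P30, 430 passed, 199 higher and 231 lower in the mutants, 59 and 91 of them by at least 2-fold. The 10 largest rises were those of Lcn2, a secreted lipocalin that binds iron carriers (log2 change 3.34), Dlk1, a transmembrane protein related to Notch ligands (3.15), Sst, the neuropeptide somatostatin (2.29), Pdyn (2.19), and Enc1, an actin-binding protein (2.18). They also included Serpina3n, a protease inhibitor (2.01), Lgals3, the lectin galectin 3 (1.89), an unnamed probe detected on 0 of 8 control arrays (at least 2.49-fold), another unnamed probe (1.78), and Caln1, a calcium-binding protein (1.57). Their standard errors lay between 0.21 and 0.48, and Lcn2 was detected on 1 of 8 control arrays, Dlk1 on 3 of 8 and the latter unnamed probe on 5 of 8.

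The 10 largest falls at P30 were those of Kcnh3, a voltage-gated potassium channel (log2 change -2.59), Egr2, a zinc finger immediate early transcription factor (-2.39), Snx7, a sorting nexin (-2.09), Nrgn (-2.06) and Ccn4, a secreted matricellular protein (-1.95). They also included Fgf10, a fibroblast growth factor (-1.92), Fosb, a subunit of AP-1 (-1.90), Arc, a regulator of synaptic strength (-1.88), an unnamed probe and Chrna10, a nicotinic acetylcholine receptor subunit. The last pair was detected on all 8 control arrays and on 0 of 8 mutant arrays, with levels at least 2.76-fold lower for the unnamed probe and at least 2.21-fold lower for Chrna10. Kcnh3 was detected on 2 of 8 mutant arrays, Fosb on 3, Egr2 and Fgf10 on 6 and Snx7 and Arc on 7, so their fitted falls depend in part on the background. Second probes gave smaller falls for Ccn4 (-0.83) and Fgf10 (-1.32). Standard errors of the falls lay between 0.16 and 0.34.

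Granule cell markers fell as a list at P30 by a mean of -0.79 (SE 0.10), -0.86 on chip A and -0.73 on chip B, with all 8 mutants below every control. This list had a camera adjusted p = 0.000229 (or adjusted p = 0.0113 with an estimated correlation, over a range of 0.00013 to 0.0113 in 26 alternatives). Of 5 measured members 3 fell, also 3 adjusted over the list alone: Nrgn, Gng4 and Pbx3, a homeodomain transcription factor (-0.63, SE 0.16). These 3 members made up nearly all of the list mean. Immediate early genes fell as a list by -1.11 (SE 0.27), -1.58 on chip A and -0.65 on chip B (camera adjusted p = 1.03e-07, but adjusted p = 0.057 with an estimated correlation, over a range of 2.05e-11 to 0.057). Of 10 measured members 4 fell (7 adjusted over the list alone): Egr2, Fosb, Arc and Npas4, an activity-dependent transcription factor (-1.50, SE 0.37).

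Neuropeptides rose as a list by a mean of 0.84 (SE 0.09), 0.91 on chip A and 0.77 on chip B, in all 8 mutants above every control. Its camera adjusted p = 9.52e-08 (or adjusted p = 0.0113 with an estimated correlation, over a range of 1.04e-08 to 0.0113). Of 11 measured members 5 rose and 1 fell (6 and 1 adjusted over the list alone). Those higher were Sst, Pdyn, Tac1, the precursor of substance P (1.49, SE 0.22), Trh, the thyrotropin-releasing hormone (1.19, SE 0.22), and Npy, neuropeptide Y (0.76, SE 0.15). Cartpt fell by 0.69 on the log2 scale (SE 0.18). Periglomerular and dopaminergic markers rose as a list by 0.36 (SE 0.08), 0.49 on chip A and 0.24 on chip B (camera adjusted p = 0.0225, but adjusted p = 0.0886 with an estimated correlation). Of 9 members 4 rose and 1 fell (6 and 2 adjusted over the list alone). Slc6a3, the dopamine transporter (1.35, SE 0.16), Trh, Ddc, the enzyme that makes dopamine from its precursor (1.00, SE 0.24), and Th (0.70, SE 0.20) rose. Kcnip1, a potassium channel partner, fell by 0.98 on the log2 scale (SE 0.15). The periglomerular list at P30 did not pass on chip B alone (adjusted p = 0.159) or without mutant replicate 7 (adjusted p = 0.0512), over a range of 0.0125 to 0.159 in 26 alternatives.

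Glial lists moved with these groups at P30. Microglial genes rose as a list by 0.60 (SE 0.15), 0.80 on chip A and 0.40 on chip B (camera adjusted p = 3.84e-05, but adjusted p = 0.057 with an estimated correlation, over a range of 2.11e-06 to 0.057). Of 10 members 4 rose (7 adjusted over the list alone), the complement genes C1qa (1.06, SE 0.27), C1qb (1.06, SE 0.28) and C1qc (0.96, SE 0.23) and the microglial receptor Trem2 (0.80, SE 0.23). Of all 10 changes 9 were positive and 1 negative. P2ry12, another member, stood at 9.15 in P30 controls and 8.89 in P30 mutants with both ages processed together. Mutant replicates 1 and 2, which stood apart, carried part of the rise of the list. C1qa reached 8.58 and 8.31 on them and at most 7.36 on the other mutant arrays. Without them and control replicate 4 the list still passed (adjusted p = 0.000992), at a mean of 0.45 (SE 0.09), with C1qa at 0.77 and C1qc at 0.71. C1qa, detected on 7 of 8 control arrays, did not pass without normexp (adjusted p = 0.0726) or on either chip alone (0.103 and 0.178), over a range of 0.0125 to 0.178 in 8 alternatives. Astrocyte markers rose as a list by 0.33 (SE 0.07), 0.32 on chip A and 0.33 on chip B (camera adjusted p = 0.017, but adjusted p = 0.057 with an estimated correlation and 0.0721 on chip B alone, over a range of 0.0059 to 0.0721). Gfap was the 1 of 9 members that rose (2 adjusted over the list alone). Genes of radial glia and stem cells rose by 0.37 (SE 0.07), 0.32 on chip A and 0.41 on chip B (camera adjusted p = 0.00368, or adjusted p = 0.0491 with an estimated correlation, over a range of 0.00144 to 0.0491). In this list 2 of 12 members were up, also 2 adjusted over the list alone: Tnc, the matrix protein tenascin C (1.11, SE 0.21), and Vim, the filament protein vimentin (0.82, SE 0.19). Other Tnc probes gave 0.79 (adjusted p = 0.0248) and 0.17 (adjusted p = 0.738) when every probe was tested. Olfactory ensheathing glia markers rose by 0.34 (SE 0.08), 0.43 on chip A and 0.25 on chip B. The camera adjusted p = 0.0225 did not hold in every alternative (adjusted p = 0.057 with an estimated correlation, 0.181 on chip B alone and 0.0512 without mutant replicate 7, over a range of 0.0111 to 0.181). Of 7 members 2 rose (3 adjusted over the list alone), Frzb, a secreted Wnt antagonist (0.75, SE 0.21), and Npy, which also stands in the neuropeptide list. Frzb (limma adjusted p = 0.0464) did not pass without normexp (adjusted p = 0.0553), with median scaling (0.173), with the deposited normalized values (0.069), without the arrays standing apart (0.0582) or on either chip alone (0.063 and 0.668), over a range of 0.0379 to 0.668. Npy did not pass with median scaling (adjusted p = 0.0912) or on chip B alone (0.264), over a range of 0.000979 to 0.264. The oligodendrocyte and myelin list had 0 of 11 members past the threshold, also 0 adjusted over the list alone, and a mean change of -0.04 (SE 0.11; camera adjusted p = 0.973).

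Lists of other neurons and of signalling targets also rose at P30. Markers of striatal and septal neurons rose by 0.38 (SE 0.04), 0.40 on chip A and 0.36 on chip B (camera adjusted p = 0.00704, or adjusted p = 0.0491 with an estimated correlation, over a range of 0.00365 to 0.0491). Of 8 members 2 rose (4 rose and 1 fell adjusted over the list alone). These were Tac1 and Ppp1r1b, a phosphatase inhibitor of dopamine-responsive neurons (0.81, SE 0.17). The other Ppp1r1b probe gave 0.34 (adjusted p = 0.425 when every probe was tested). Mitral and tufted cell markers rose by 0.29 (SE 0.07), 0.27 on chip A and 0.30 on chip B (camera adjusted p = 0.0387, but adjusted p = 0.106 with an estimated correlation). Of 10 members 2 rose and 1 fell, the same adjusted over the list alone. Slc17a7, a vesicular glutamate transporter (1.12, SE 0.21), and Tbr1, a transcription factor of glutamatergic neurons (0.95, SE 0.21), rose and Doc2g fell (-0.72, SE 0.20). The mitral list did not pass without normexp background correction (0.0513), on chip A alone (0.118), or without control replicate 5 (0.0749) or 8 (0.0609) or mutant replicate 3 (0.0785), 6 (0.0812) or 7 (adjusted p = 0.0889), over a range of 0.0194 to 0.118. Targets of the Wnt, Shh and BMP pathways rose by 0.39 (SE 0.10), 0.42 on chip A and 0.35 on chip B (camera adjusted p = 0.00169, but adjusted p = 0.106 with an estimated correlation, over a range of 0.000707 to 0.106). Of 10 members 3 rose (7 adjusted over the list alone), the BMP-responsive genes Id4 (0.83, SE 0.19), Id3 (0.79, SE 0.21) and Msx1 (0.55, SE 0.16). Cortical excitatory neuron markers did not pass as a list (camera adjusted p = 0.056; 0.0299 without control replicate 7, 0.0433 without mutant replicate 1 and 0.0259 without mutant replicate 5, over a range of 0.0252 to 0.391). Of its 6 members Lmo4 (0.89) and Tbr1 rose and Mef2c fell by 0.83 on the log2 scale, 2 and 1 also adjusted over the list alone.

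Single members changed in further lists that camera did not call at P30. Among 16 migration cues and receptors (camera adjusted p = 0.656), Prok2, the ligand of Prokr2 (log2 change -1.77, SE 0.22), Gdnf, a neurotrophic factor (-1.08, SE 0.17), and Prokr2 (-0.96, SE 0.25) fell and the chemokine receptor Cxcr4 rose (0.73, SE 0.18). Prok2 was detected on 3 of 8 mutant arrays, Gdnf on 2 of 8 mutant arrays and Cxcr4 on 6 of 8 control arrays, so these fitted changes depend in part on the background. Adjusted over the list alone, 4 were up and 3 down. Of 14 genes of synapses and mature neurons (camera adjusted p = 0.762), the kinase subunits Camk2b (-1.24) and Camk2a (-0.78, limma adjusted p = 0.0474) fell, and 1 rose and 2 fell adjusted over the list alone. Meis2 fell (-0.67) among 13 interneuron lineage transcription factors (2 fell adjusted over the list alone; camera adjusted p = 0.583). Camk2a did not pass without normexp (adjusted p = 0.0505) or with the deposited normalized values (0.079), over a range of 0.0226 to 0.297 in its 8 alternatives. Meis2 did not pass with the deposited values (adjusted p = 0.0526), over a range of 0.00663 to 0.261. Foxc1 rose (0.79, detected on 5 of 8 control arrays) among 11 meningeal genes (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.429). Cdkn1a, a cyclin-dependent kinase inhibitor, fell (-1.30) among 12 p53 targets (1 adjusted over the list alone, camera adjusted p = 0.66). Other Cdkn1a probes gave -0.97 (adjusted p = 0.0132) and -0.80 (adjusted p = 0.29) when every probe was tested. B2m, the light chain of MHC class I, rose (0.71) among 9 reference genes (2 rose adjusted over the list alone; camera adjusted p = 0.894). It did not pass with median scaling (adjusted p = 0.186), without the arrays standing apart (0.0844) or on either chip alone (0.111 and 0.35), over a range of 0.0138 to 0.35. Atf3, a stress-responsive transcription factor, was detected on 0 of 8 mutant arrays and was at least 1.27-fold lower, the 1 of 10 stress and RNA quality genes that passed (2 fell adjusted over the list alone; camera adjusted p = 0.14). No member passed among neuroblast and immature neuron markers (3 of 10 rose adjusted over the list alone, camera adjusted p = 0.0915). That list passed without mutant replicate 2 (adjusted p = 0.0368), without the arrays standing apart (0.0257) and on chip B alone (0.00687). On chip A alone it did not (adjusted p = 0.761), over a range of 0.00687 to 0.761. Over arrays its mean was 0.25 (SE 0.07), higher in the mutants (unadjusted exact permutation p = 0.00249, two-sided). The cortical list (0.30, SE 0.09, exact permutation p = 0.00699) and the proliferation list (0.20, SE 0.09, exact permutation p = 0.0286) were also higher, unadjusted. No member passed among olfactory sensory neuron axon markers (1 of 9 rose adjusted over the list alone, camera adjusted p = 0.14). The lists for GABA synthesis and transport, proliferation, endothelium and pericytes, blood and sex-linked genes had 0 members past the threshold, also 0 adjusted over the list alone, with camera adjusted p between 0.133 and 0.973. The proliferation list was higher on chip B alone (adjusted p = 0.00899) and not on chip A alone (adjusted p = 0.421), the lowest and highest of its 26 alternatives. Tshz3 changed by -0.05 (SE 0.16, adjusted p = 0.933, 0 adjusted over the list alone).

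Chip A alone called 137 genes and chip B alone 194 at P30, and chip as a fixed block called 576 (282 higher, 294 lower). Without control replicate 4 and mutant replicates 1 and 2, which lay farthest from the other arrays on the first principal component, 520 genes passed, 347 of them among the 430. Of 46 named genes Frzb, Id3 and B2m no longer did.

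**Figure D2:**
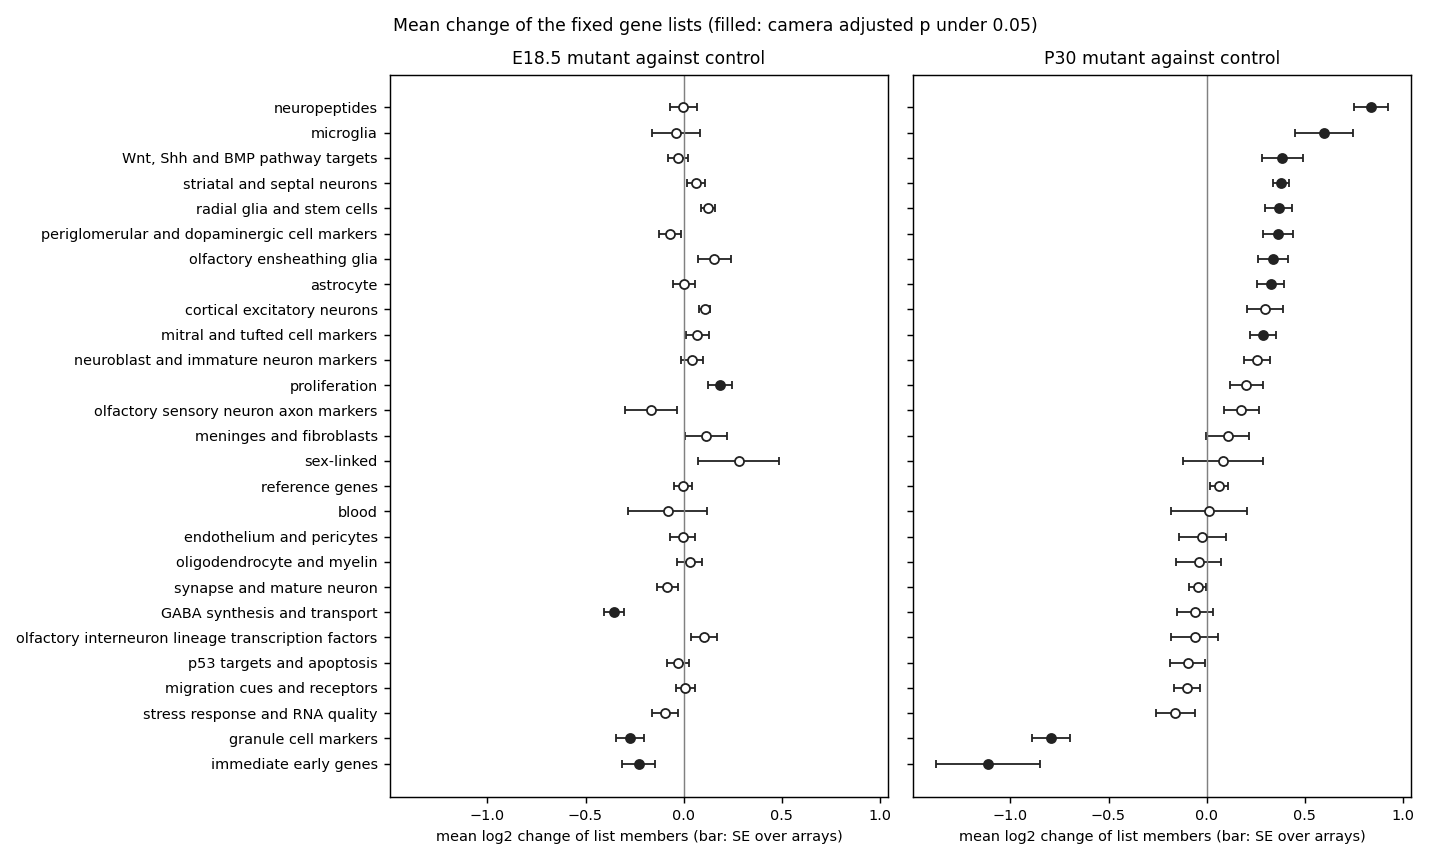
Mean log2 change of the members of each fixed gene list, mutant against control, at E18.5 (left) and P30 (right), with bars for the standard error over arrays and filled points for a camera adjusted p under 0.05. The GABA list stands at -0.35 at E18.5 and at -0.06 at P30, and the granule cell list at -0.27 and -0.79.

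The same genes were then compared between the ages, whose comparisons share no arrays. Of 9613 genes measured at both ages, 36 passed at both, 35 of them (97.2%) in the same direction. Down at both ages were 32 genes, against 1.18 for independent lists (Fisher exact test, two-sided, odds ratio 76.5, p = 3.31e-40), including Ntsr1, Sp7, Crabp1, Prokr2, Gng4, Nrgn, Kcnh3 and Snx7. Up at both ages were 3 genes, Fhdc1, Npr3 and Wnt9b, against 0.157 (odds ratio 30.3, p = 0.00039, Fisher exact test). Th was the 1 gene that passed in opposite directions, down at E18.5 and up at P30. Of the 62 genes called at E18.5 and measured at both ages, 53 had the same sign at P30, while over all genes the log2 changes at the ages correlated weakly (Pearson r = 0.0971 across genes, which are not independent replicates).

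The genes next to Tshz1 on chromosome 18 were examined because the mutant alleles come from a mixed strain background. Among the 60 measured neighbours at E18.5, 0 passed (0.584% of the other genes; Fisher exact test, two-sided, p = 1). Among 59 measured neighbours at P30, Zfp236 (log2 change -0.93) and Neto1 (-1.08) passed, 3.39% against 4.34% of the other genes (Fisher exact test, odds ratio 0.774, 95% interval 0.0912 to 2.94, p = 1). Only 10 and 9 of these neighbours lay on the far side of Tshz1, the rest on the other side.

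**Figure D3:**
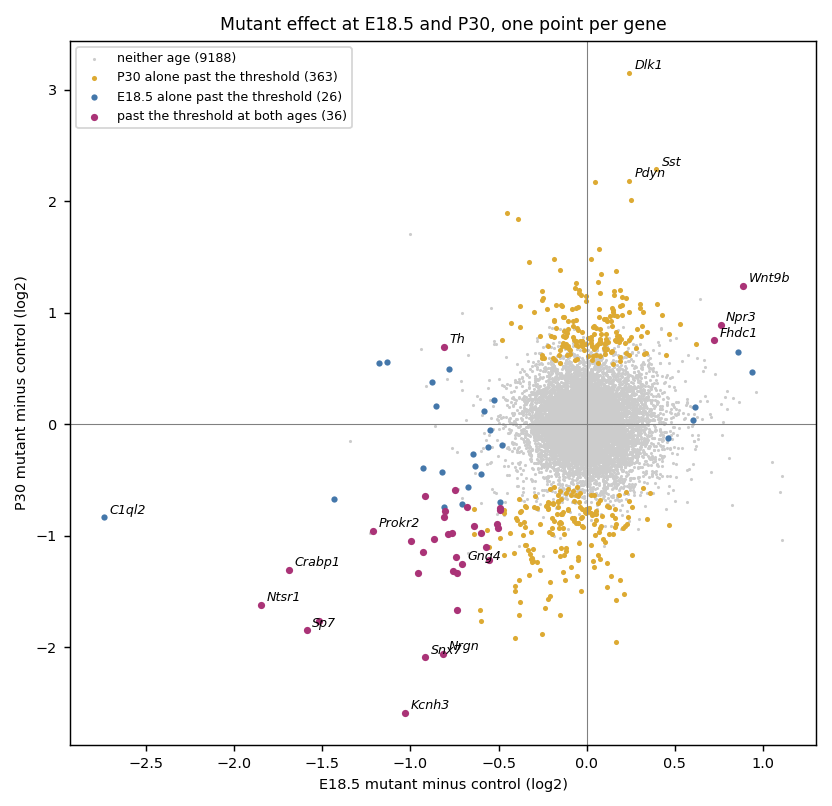
Log2 change in E18.5 mutants (horizontal axis) against that in P30 mutants (vertical axis), 1 point per gene measured at both ages. Of these genes 26 passed at E18.5 alone, 363 at P30 alone, 36 at both and 9188 at neither.

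A further comparison tested whether the mutant effect itself differed between the ages, on all 32 arrays normalized together. Effects on Pdyn and Dlk1 were more positive at P30 and those on Kcnh3 and Ccn4 more negative. Of 11312 genes tested, 209 passed, 117 with a more positive and 92 with a more negative effect at P30. In the positive direction the smallest p belonged to Pdyn (difference of log2 changes 1.91, SE 0.24), Dlk1 (3.36, SE 0.44), Pdlim4, a LIM domain protein (1.49, SE 0.20), Htr3a, a serotonin-gated ion channel subunit, and Gfap. Their limma adjusted p ran from 2.36e-06 to 7.75e-06. In the negative direction they belonged to an unnamed probe, Chrna10, Ccn4 (-2.32, SE 0.21), Slc38a8, an amino acid transporter, and Kcnh3 (-2.28, SE 0.23). These had limma adjusted p from 8.71e-13 to 2.7e-08. Htr3a, Gfap, Slc38a8, Chrna10 and the unnamed probe were detected on 0 of 8 arrays of at least 1 group, so no size is given for their differences. Kcnh3 was detected on 2 of 8 P30 mutant arrays and Dlk1 on 3 of 8 P30 control arrays, so their differences depend in part on the background. Th differed by 1.46 (limma adjusted p = 0.000249).

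Of 27 lists, 7 differed between the ages. Neuropeptides were more positive at P30 by a mean of 0.83 (camera adjusted p = 3.15e-09, or adjusted p = 0.000634 with an estimated correlation), with Pdyn, Sst, Tac1 and Trh the 4 of 11 members past the threshold (6 adjusted over the list alone). Microglial genes differed by 0.69 (camera adjusted p = 0.000159; 2 of 10 members past the threshold, 5 adjusted over the list alone) and Wnt, Shh and BMP targets by 0.40 (0.00624; 0 of 11, 6 adjusted over the list alone). Astrocyte markers differed by 0.31 (0.0497; 1 of 9, 2 adjusted over the list alone) and immediate early genes by -0.97 (1.39e-05; 3 of 10, 4 adjusted over the list alone). Each of these 4 lists had an adjusted p = 0.0843 with an estimated correlation. The mean of the immediate early list depends in part on the background. At E18.5 Egr2 was detected on 2 control and 0 mutant arrays and Fosb on 1 and 0. The astrocyte mean does so through Gfap, detected on 0 arrays of both E18.5 groups. Periglomerular markers differed by 0.42 (camera adjusted p = 0.0111; 3 of 9, all positive; 4 and 2 adjusted over the list alone). Granule cell markers differed by -0.44 (0.0208; 0 of 6, 3 adjusted over the list alone). Both had an adjusted p = 0.0722 with an estimated correlation. The change of the GABA list, which passed at E18.5 alone, did not pass this test (mean difference 0.29, camera adjusted p = 0.154, 0 of 5 members also adjusted over the list alone). In the other lists camera adjusted p lay between 0.104 and 0.998. The members past the threshold were Tnc among radial glia genes, Slc17a7 among mitral markers, Tac1 among striatal markers and B2m among reference genes in the positive direction, and Gdnf, Prok2 and Atf3 in the negative direction. The ages also differed in chip and in the alleles carried, and the count rose to 364 with chip and to 380 with the replicate number as a block.

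The last comparison set the P30 controls against the E18.5 controls and so took in the maturation of the bulb together with the differences in chip and alleles. Myelin genes and activity-regulated genes were far higher at P30 and cell cycle genes far lower. Mbp, a major protein of myelin, rose from 8.28 ± 0.49 to 14.84 ± 0.18 (log2 normalized intensity, mean ± SD, n = 8 per group), a 94.4-fold higher level (limma adjusted p = 1.66e-28). Cck rose by 6.06 on the log2 scale (SE 0.14), a 66.5-fold higher level (limma adjusted p = 1.03e-28). Cdk1, the kinase that drives mitosis, was detected on 8 of 8 arrays at E18.5 and 0 of 8 at P30, at least 14.6-fold lower (limma adjusted p = 2.77e-22).

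Of 11312 genes tested, 2698 changed by at least 2-fold, 1278 higher and 1420 lower at P30. The 10 largest rises also included Ntsr2, a neurotensin receptor of astrocytes (log2 change 6.33), the myelin genes Mag (6.26), Mobp (5.55) and Mog (5.20), and S100a5, a calcium-binding protein of olfactory sensory neurons (6.26). They were completed by Egr4 (5.16), Vip, a neuropeptide (at least 34.7-fold), and Fa2h, an enzyme of myelin lipid synthesis (at least 29.6-fold), the latter pair detected on 0 of 8 E18.5 arrays. On the 8 E18.5 arrays, Mobp and Mog were detected on 1, Ntsr2 on 3 and Mag on 4, so their fitted rises depend in part on the background. The 10 largest falls were those of 3 unnamed probes (-6.10 for the first, and at least 19.2-fold and 9.58-fold for the others, which were detected on 0 of 8 P30 arrays) and of Cdk1. With them were the mitotic genes Pbk (-4.71, detected on 3 of 8 P30 arrays), Cenpa (-4.21), Prc1 (-4.15) and Top2a (at least 9.59-fold), Islr2 (-4.65) and Tbr1 (-4.15). Scaling each array to a common median in place of quantile normalization put the median change of all genes at -0.53 on the log2 scale and gave 557 higher and 3447 lower genes (13.9% higher, against 47.4%). Under the other scalings that median lay between -0.02 and 0.01.

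Of 27 lists, 12 differed between the ages, and none of the 12 changed sign under the other scalings. The proliferation list fell by a mean of -2.59 (13 of 15 members; camera adjusted p = 2.88e-12). Neuroblast and immature neuron markers fell by -1.36 (7 of 12 fell and Ncam1 rose; 6.19e-05) and meningeal genes by -1.37 (10 of 12 fell and Ptgds rose; 0.000532). Oligodendrocyte and myelin genes rose by 3.33 (9 of 11 rose and Pdgfra, a receptor of their precursors, fell; camera adjusted p = 3.66e-08). Immediate early genes rose by 3.13 (8 of 10, such as Fos by 4.43; camera adjusted p = 9.78e-07) and astrocyte markers by 1.93 (5 of 9, such as Gfap, at least 10.6-fold; 4.6e-05). Neuropeptides rose by 1.63 (7 of 11 rose and Nts fell; camera adjusted p = 0.00407) and genes of GABA synthesis and transport by 1.23 (3 of 5, such as Gad1 by 2.64; 0.00731). Periglomerular and dopaminergic markers rose by 1.03 (5 of 9, such as Slc6a3 by 2.19; camera adjusted p = 0.0034) and genes of synapses and mature neurons by 0.89 (5 of 14; 0.000954). These 10 also passed with an estimated correlation. Microglial genes rose by 1.04 (5 of 10; camera adjusted p = 0.00415) and endothelial and pericyte genes fell by -0.68 (4 of 12 fell and Rgs5 rose; 0.0289). Each had an adjusted p = 0.141 with an estimated correlation, and the endothelial list gave 0.139 with median scaling. The lists that camera did not call had adjusted p between 0.0999 and 0.988. Of these, mitral and tufted cell markers had 1 member higher and 5 lower of 10, cortical markers 1 and 4 of 6, and olfactory sensory neuron axon markers 4 and 1 of 9. Radial glia genes had 0 higher and 4 lower of 12, migration cues and receptors 3 and 6 of 21, and granule cell markers 2 and 1 of 6. Interneuron transcription factors had 1 higher and 2 lower of 13, ensheathing glia 1 and 1 of 7, striatal markers 1 and 0 of 9 and blood 0 and 2 of 7. Sex-linked genes had 1 and 0 of 4, p53 targets 2 and 0 of 12, Wnt, Shh and BMP targets 1 and 2 of 11, stress genes 3 and 2 of 12 and reference genes 0 and 1 of 9. Tshz3 changed by -0.53. In every list of this comparison the counts adjusted over the list alone were the same.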

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

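The tests of forebrain tissue, of exchanged labels and of genes on other chromosomes were chosen after the results were seen, as were the list means without the arrays standing apart, and the gene counts without those arrays after the principal components and the main counts.

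At P30, the granule cell list was lower, nearly all of it through Nrgn, Gng4 and Pbx3, while markers of many other cell groups were higher. With an estimated correlation the radial glia and striatal lists still passed (adjusted p = 0.0491 each), and those of microglia, astrocytes and ensheathing glia (adjusted p = 0.057 each), periglomerular cells (0.0886) and mitral cells (0.106) did not. A lower share of granule cells would raise the other cell types alike. Microglial genes exceeded oligodendrocyte and myelin genes by 0.64 (SE 0.21) on the log2 scale, more than the margin fixed beforehand. This argues against that share as the whole account but does not exclude it. Whether the microglial mean measured the share of microglia was not tested. The list member P2ry12 was not higher in the P30 mutants (8.89, against 9.15 in P30 controls). The lists were picked as the highest and lowest of those compared, and the SE does not allow for that choice. Control replicate 4 and mutant replicates 1 and 2, which stood apart, did not carry the count, since 520 genes passed without them. They carried part of the microglial rise, but microglial genes still exceeded oligodendrocyte and myelin genes without them, by 0.44 (SE 0.14). Forebrain tissue taken beside the bulb remained open: the 14 members of the cortical and striatal lists had a mean change of 0.35 (SE 0.05), with Tac1, Lmo4, Tbr1 and Ppp1r1b higher and Mef2c lower.

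At E18.5, the list of GABA synthesis and transport and the granule cell list were lower. The granule cell list rested mostly on Gng4 and Nrgn and did not pass with an estimated correlation (adjusted p = 0.126). A lag of the mutant bulb in its maturation stayed open, and the covariance of the mutant effect with the age change was -0.0303 with odd-numbered controls in the mutant effect and -0.0316 with even-numbered ones. In comparison, 6 of 100 regroupings were as low, the lowest at -0.053. Of the 55 genes that fell, 29 rose at least 2-fold with age (52.7%, against 11.3% of all genes) and 2 fell. Without control replicates 6 and 8, which stood apart, 50 genes passed. The GABA list (camera adjusted p = 0.000219) and the granule cell list (camera adjusted p = 0.00282) still passed, but Gad1 and Nrgn no longer did on their own.

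Of the genes that passed at both ages, 97.2% changed in the same direction, which argues against P30 labels exchanged in error. That reading needs the E18.5 labels to hold and the mutant effect to have the same direction at both ages. A strain difference around the mutant alleles remained open for genes near Tshz1. There the odds ratio of a call at P30 was 0.774 with up to 50 genes on each side and 1.76 with up to 100. Of the 34 genes shared in the same direction that could be placed, 2 (Adamts19 and Camk2a) lay on the chromosome of Tshz1 and 32 on others. Those 32 are not linked to Tshz1 themselves. Most genes lie on other chromosomes, however, so this count cannot exclude a strain difference behind the shared genes.

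Random regrouping of the arrays was compared with the real grouping, itself among the 100 splits. At E18.5, 2 of 100 splits gave as many genes as the real 63, with the highest other at 95, and among splits that part the replicate pairs only the real one did, with the highest other at 3. At P30, 1 of 100 gave as many as 430, with the highest other at 24 (95 among splits that part the pairs). For the difference between the ages, 2 of 100 gave as many as 209, with the highest other at 494, and for the age comparison 1 of 100 gave as many as 2698, with the highest other at 1622. A split by chip gave 1312 genes at E18.5 and 971 at P30, more than genotype did, and with chip as a block genotype gave 75 and 576.

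Each group of arrays was searched for an array far from the other 7. The search covered the named genes that passed or stood for a list called by camera, the share of probes detected and the correlation within the group. In 15 of these 160 groups of values, against about 1 in 20 by chance, such an array was found, all of them at P30. Other named genes were not searched. Control replicate 8 was such an array for Lcn2 (6.38), Tac1 (7.97), Ppp1r1b (8.71), Cdkn1a (10.82), B2m (11.13) and Meis2 (11.80). Mutant replicate 1 was such an array for Slc6a3 (8.91), Lgals3 (10.78), Serpina3n (12.16) and Cdkn1a (12.29). The others were mutant replicate 7 for an unnamed probe (5.08) and Nrgn (6.41), mutant replicate 8 for Fosb (7.08), control replicate 1 for Serpina3n (6.99) and control replicate 2 for Tnc (5.89).

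The mutant effect differed between the ages for 38 of the named genes, with adjusted p from 8.71e-13 to 0.0441. For 14 of them at least 1 group had the gene detected on 0 of 8 arrays, so their fitted values, given last, are not sizes. It was more negative at P30 for Ccn4 (-2.32), Kcnh3 (-2.28), Snx7 (-1.37), Arc (-1.72), Prok2 (-1.64) and Fgf10 (-1.87). It was more positive for the peptides and transmitter genes Pdyn (1.91), Sst (1.76), Tac1 (1.58), Slc6a3 (1.26), Th (1.46) and Slc17a7 (1.32), and for the glial and immune genes Lgals3 (2.41), B2m (0.89), Tnc (1.20), C1qb (1.38) and C1qc (1.09). It was also more positive for Dlk1 (3.36), Pdlim4 (1.49), Enc1 (2.02), Caln1 (1.46), Crhbp (1.51) and C1ql2 (1.60). The fitted values that are not sizes were those of 3 unnamed probes (-2.91, 2.66 and 1.82), Chrna10 (-2.55), Slc38a8 (-1.85), Egr2 (-2.39), Fosb (-2.14), Gdnf (-1.40), Atf3 (-1.21), Gfap (1.53), Htr3a (1.73), Cpa3 (1.44), Wnt9b (0.94) and Nmbr (1.77). Lcn2 (4.02) is no size either, since it was detected on at most 2 of 8 arrays in all groups but the P30 mutants. Those of Kcnh3, Prok2, Dlk1, Crhbp, C1ql2, Fgf10, Snx7 and Arc depend in part on the background, since 1 group or more had them detected on only 2 (Kcnh3) to 7 of 8 arrays. The 7 lists that differed were periglomerular markers (0.42), granule cell markers (-0.44), astrocyte markers (0.31), microglia (0.69), immediate early genes (-0.97), neuropeptides (0.83) and Wnt, Shh and BMP targets (0.40). With an estimated correlation only neuropeptides passed (adjusted p = 0.000634), while periglomerular and granule cell markers (adjusted p = 0.0722 each) and the other 4 lists (adjusted p = 0.0843 each) did not. The values of the immediate early and astrocyte lists depend in part on the background, through Egr2, Fosb and Gfap at E18.5.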

How the results depend on the processing

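The alternatives were fixed before the data were examined, except those without the arrays standing apart, which were chosen after the principal components and the main counts were seen. At E18.5, against 63 genes, 14 of 17 alternatives stayed within 1.5-fold, while chip A alone gave 41, chip B alone 5 and all 32 arrays processed together 26, and leaving out single arrays gave 50 to 74. The Xist level as a covariate for sex gave 74 and the replicate block, which pairs samples, gave 62 (11 higher, 51 lower) and changed no call of a named gene or list other than those given with the results. Of its 62 genes, 51 were among the 63. At P30, against 430 genes, stricter detection gave 223, array weights 736, chip A alone 137, chip B alone 194 and all 32 arrays together 1030, leaving out single arrays gave 340 to 469, the Xist covariate 406 and the replicate block 539 (266 higher, 273 lower; Frzb adjusted p = 0.0684). At P30 same-numbered samples also lay on the same chip. Their r lay between -0.07 and 0.417 over 8 pairs, and 4 controls and 2 mutants correlated best with their own number. At E18.5 these counts were 2 and 3.

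For the difference between the ages, against 209 genes, median scaling gave 84, stricter detection 70, array weights 342, chip as a block 364 and the replicate block 380, and leaving out single arrays gave 166 to 271. For the age comparison, against 2698 genes, leaving out background correction gave 1394, stricter detection 1177 and dropping the fold condition 6992. Of the 4 lists called at E18.5, 1 remained with an estimated correlation and 2 with chip A alone or without control replicate 4, control replicate 5 or mutant replicate 6. Of the 11 lists called at P30, 4 remained with an estimated correlation, and leaving out single arrays gave 8 to 12. The immediate early gene list at E18.5 also did not pass without background correction (adjusted p = 0.0532), with median scaling (0.064), with the deposited normalized values (0.054), on chip A alone (0.055), on chip B alone (0.198) or without the arrays standing apart (0.0624).

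Among neighbours of Tshz1, taking up to 100 genes on each side gave 2 of 110 called at E18.5 (Adamts19 and Camk2a) and 8 of 109 at P30. The E18.5 share was 1.82%, against 0.568% of the other genes (odds ratio 3.24, Fisher exact test, two-sided, p = 0.134). The P30 share was 7.34%, against 4.30% (odds ratio 1.76, Fisher exact test, two-sided, p = 0.147). Adamts19 and Camk2a were also among the 8 at P30. Chip as a block gave 1 of 60 and 4 of 59, against 0 of 60 and 2 of 59. The overlap of 35 genes became 75 at an unadjusted p under 0.01 and 43 with chip as a block. The named genes were followed in 8 alternatives per age. In these, each of the 25 called at E18.5 (24 measured on chip A alone) and the 46 called at P30 (45 measured on chip B alone) kept its direction. Calls were lost for 10 of 24 genes on chip A and 21 of 25 on chip B at E18.5, and for 19 of 46 on chip A and 16 of 45 on chip B at P30. At P30 the calls of Camk2a, Frzb and C1qa were lost without normexp, those of Npy, Frzb and B2m with median scaling, and those of Meis2, Camk2a and Frzb with the deposited normalized values. Without the arrays standing apart, calls were lost for 9 of 25 genes at E18.5 and, at P30, for Frzb, Id3 (adjusted p = 0.0727) and B2m. The replicate block lost 5 of 25 at E18.5. At E18.5 the calls of Pgm5, Cck and the unnamed probe that rose were lost without normexp. Besides Th, median scaling at E18.5 lost Slc32a1 and Camk2a (adjusted p = 0.0609 each) and Cck and the unnamed probe that rose (adjusted p = 0.092 each). The alternatives for the level of Tshz1 were not run, because no probe used here was named Tshz1.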
